A study of Mus musculus with 31 samples.

How the data were processed

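RNA was measured in hybrids of the mouse strains B6 and JF1 at 5 stages: ESCs, in vitro day 12, in vitro day 21, cortex at E13.5 and cortex at P0. Per the labels, hybrid ESCs came from blastocysts of both reciprocal crosses, and the B6 parent of the cell lines carried a green fluorescent reporter driven by Oct4. Cells were differentiated in defined medium with cyclopamine, an inhibitor of Hedgehog signalling, in an early window, and total RNA was made into stranded polyadenylated RNA libraries. Per the labels, the submitters' processing notes name CASAVA 1.8.2, Novoalign, HTSeq and edgeR, without versions for the latter 3, on the mm9 build.

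The deposited tables hold raw counts, with no normalization: for each gene and sample, the number of sense-strand read bases that carry the maternal or the paternal allele, summed over the gene's strain differences. The authors took bases at strain differences with SAMtools mpileup 0.1.18, and assigned them to genes of the UCSC refFlat annotation together with 11 mitochondrial genes. A strain difference inside 2 genes is counted by the authors under a joined name. The authors' description starts from 12508968 strain differences. It states that 6252 were removed from all samples because the B6 parent of the in vitro crosses carried sequence of other strains there, while its summary gives 37985, so the number removed is uncertain. Their filter pooled the 12 in vitro libraries and took positions covered by more than 50 reads, with the B6 base below 10% and the JF1 base above 40%. Because 1 read that covers several strain differences adds several read bases, read bases are not independent molecules, and intervals and floors cover counting error only. An alternative with all counts divided by 3 addresses this.

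Tables held 14813 features for ESCs, 15450 for day 12, 16074 for day 21, 15456 for E13.5 and 16120 for P0. Depth was 5192382 to 8618253 read bases per library, of which 10.6% to 22% were mitochondrial and 12.9% to 24% fell in the 10 most abundant genes. The B6 allele held 50.6% to 52.1% of autosomal read bases. Chromosomes were taken from the deposited tables, and 12 features that share a symbol were kept apart by strand and chromosome. The GRCm38 annotation gave gene order, by gene number, for the test of neighbouring genes. The libraries of non-hybrid E14 cells at days 12 and 21 were not analysed here. Samples were grouped by stage and cross from the labels.

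Allelic tests used edgeR 4.0.16 in R 4.3.3, with 2 columns per library, 1 for each allele, and the same library size for both. The model had a term for each library, a term for strain and a term for parent, and the parental term gave maternal over paternal. Genes on autosomes with a mean of at least 20 read bases per library were tested with the quasi-likelihood test with robust dispersion, and p-values were adjusted by Benjamini-Hochberg. A gene passed at an adjusted p of 0.05. Differences in parental bias between stages were contrasts in a joint fit of the 5 stages, with the floor met in both stages. Expression used the sum of both alleles, TMM scaling and a model of stage and cross. The same floor and test applied, over genes of all chromosomes, mitochondrial genes included. Only genes listed by the authors at both stages of a contrast were tested, with the floor on the mean over the 2 stages. Genes without a read base at 1 stage could therefore be left out of the expression counts. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation (limma 3.58.1). The X-linked share used X-linked genes with the same mean of at least 20 read bases. Single values were compared with exact permutation tests, and overlaps with Fisher's exact test. Confidence intervals are 95% Wilson intervals, except for an exact binomial interval of the pooled mitochondrial share. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the tables, gave the intervals and drew the plots.

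These 13 gene lists, the tests, the filters and the rule for named genes were fixed before the data were examined: genes known to be expressed from the maternal or from the paternal allele, pluripotency, dorsal telencephalic progenitors, cortical neurons, ventral forebrain and GABAergic neurons, caudal neural tube, glia, vascular with blood, meningeal and microglial cells, mesendoderm and other lineages, cell cycle, DNA methylation and imprint maintenance, and stress with immediate early genes. By the rule, the named genes are, for parental bias, every listed imprinted gene that passed and up to 10 unlisted genes per stage with the same side in every library. For differences they are up to 10 passing genes per contrast by size, and for strain up to 3 per direction and stage. For expression they are up to 4 passing genes per list and direction, and up to 5 rising and 5 falling outside the lists with a mean of at least 100. Some genes that the rule names are not reported here. Hells at day 12, and the libraries described as standing apart, were chosen after their values were seen.

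The fits were tested on simulated data, in which 100 genes per size were changed by a log2 of 1 or 2. Counts had the fitted trend of spread with level, but no spread particular to a gene and no dependence between read bases. Recovery and false calls in the real data can therefore be worse than the following values. The parental test recovered 87% to 97% of the changes of 1 and 99% to 100% of those of 2. For differences between stages recovery was 83% to 94% and 97% to 100%, and for expression 84% to 99% and 99% to 100%. Calls among unchanged genes numbered 5 to 16.

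Alternatives were DESeq2 1.42.0, limma on log2 ratios with a pseudocount of 1, scaling factors per allele column, DESeq2 size factors in edgeR, a mean of at least 100 read bases, no filter, autosomal genes only for expression, a block for replicate number, a test against a 2-fold change, fits of 2 stages alone against the joint fit, and leaving out each library in turn. All of these were planned. Counting genes biased by at least 10 points the same way in both crosses, and using female libraries only, were chosen after the data were seen.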

Results

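The data are allele-specific RNA sequencing of F1 hybrids between the mouse strains C57BL/6J (B6) and JF1, which differ at single bases across the genome. Hybrid embryonic stem cells (ESCs) were differentiated toward cortex in culture and sampled as ESCs, at day 12 and at day 21, and cortex was taken from hybrid embryos at E13.5 and from newborns at P0. The sample labels name the E13.5 tissue DT and the P0 tissue Ctx, while the series text calls both cortex, so the dissections may differ. In the BJ1 cross the mother was B6 and the father JF1, and in the JB6 cross the parents were exchanged. The values are counts of sequenced bases at strain differences within a gene, here called read bases, assigned to the maternal or the paternal allele. The 25 libraries analysed comprised 4 of ESCs, 4 of day 12 and 4 of day 21, each with 2 per cross, 6 of E13.5 with 3 per cross, and 7 of P0 with 4 BJ1 and 3 JB6. Depth ranged from 5192382 to 8618253 read bases per library (mean 6323163), and 13055 to 15173 genes held at least 1 read base. All in vitro libraries were labelled male, whereas 11 of the 13 in vivo libraries were labelled female. Shares below are means over libraries ± SD, folds are log2 ± standard error, and levels are read bases scaled to library size as CPM. Each standard error is the size of the fold divided by the square root of the F statistic of its test. It is approximate, and unreliable where an allele or stage has few or no read bases. The p-values measure spread between samples, and because the labels do not say whether these came from separate animals or cultures, part of that spread may be technical only. In vitro, each cross is represented by its own stem cell line, so line and cross are confounded there.

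Genes on the X chromosome were read first, because a male inherits its X from the mother. In the 14 male libraries 2.36% ± 1.19 of X-linked read bases carried the paternal label. The source of these bases, such as errors of allele assignment, was not tested. The maternal share was 98.4% ± 0.33 in the 6 in vitro BJ1 libraries and 96.5% ± 0.861 in the 6 in vitro JB6 libraries. It was 98.7% ± 0.177 in the 2 in vivo libraries labelled male and 58.6% ± 5.27 in the 11 labelled female, where it ran from 50.9% to 68.9%. In vivo, the male mean exceeded the female mean by 40.1 percentage points (exact two-sided permutation test over 78 regroupings, p = 0.0128, the smallest they can give).

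**Figure D1:**
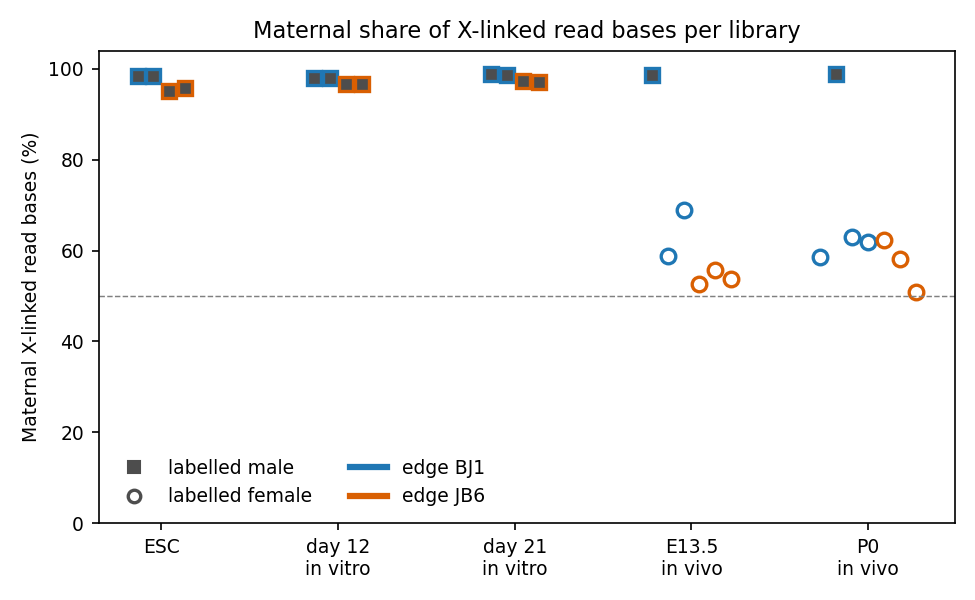
Maternal share of X-linked read bases (%, y axis) in each of the 25 libraries, by stage (x axis). Squares are libraries labelled male and open circles libraries labelled female, with the edge colour giving the cross. The 14 male libraries lie at 95.1% or above and the 11 female libraries at 68.9% or below.

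The first comparison asked which genes are read mainly from one parent's allele in cortex. H19, a non-coding RNA made from the maternal chromosome, was 99.2% ± 1.25 maternal at E13.5 (n = 6) and 99.4% ± 0.497 at P0 (n = 7). The maternal non-coding RNA Meg3 reached 99.5% ± 0.545 at P0 (adjusted p = 4.79e-05), and Cdkn1c, an inhibitor of cell division, 98.4% ± 1.47. On the paternal side, the zinc finger gene Peg3 was 0.756% ± 0.577 maternal at E13.5 and 0.195% ± 0.278 at P0, and Peg13 was 0.339% ± 0.284 and 0.197% ± 0.141. Plagl1, a growth-regulating transcription factor, was 1.84% ± 1.97 and 1.5% ± 0.967 maternal. Grb10, an adaptor that restrains growth factor signalling, was 99.6% ± 0.23 maternal at E13.5 and 73.3% ± 5.26 at P0. Several genes had a graded bias rather than a nearly complete one. Blcap was 77.7% ± 1.61 and 73.2% ± 3.75 maternal, Inpp5f 12.2% ± 3.13 and 8.08% ± 1.14, and Impact 21.1% ± 12 and 29.9% ± 13.6. At P0 the maternal share of Impact was 40.6% ± 2.75 in BJ1 (n = 4) and 15.7% ± 3.57 in JB6 (n = 3). Herc3, on the list of paternally expressed genes, was the listed gene that passed in the opposite direction, at 64.5% ± 1.94 maternal at E13.5. Among genes on neither list, Phactr2 (chromosome 10) was 67.5% ± 4.73 and Ltv1 (chromosome 10) 59.5% ± 1.58 maternal at E13.5, whereas A230057D06Rik and D7Ertd715e (chromosome 7) were 1.74% ± 2.59 and 0.317% ± 0.353. Every E13.5 and P0 library lay on the same side of 50% for each of these genes at the stages given.

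At E13.5, 49 of 9999 autosomal genes passed at an adjusted p of 0.05, 22 with more maternal and 27 with more paternal read bases, against 591 at an unadjusted p of 0.05. Of 22 tested genes on the maternal list 13 passed as maternal, and of 26 on the paternal list 23 passed as paternal. At P0, 57 of 10402 genes passed, 24 maternal and 33 paternal, against 684 at an unadjusted p of 0.05. There, 15 of 24 tested genes on the maternal list passed as maternal and 22 of 27 on the paternal list as paternal. Adjusted over the list alone, 41 of 48 listed genes passed at E13.5 and 40 of 51 at P0. At P0 Herc3 again passed as maternal, a call that was lost with limma on log2 ratios. A stricter count, chosen after the data were seen, required at least 10 points from 50% the same way in both crosses and gave 35 genes at E13.5 and 32 at P0.

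**Figure D2:**
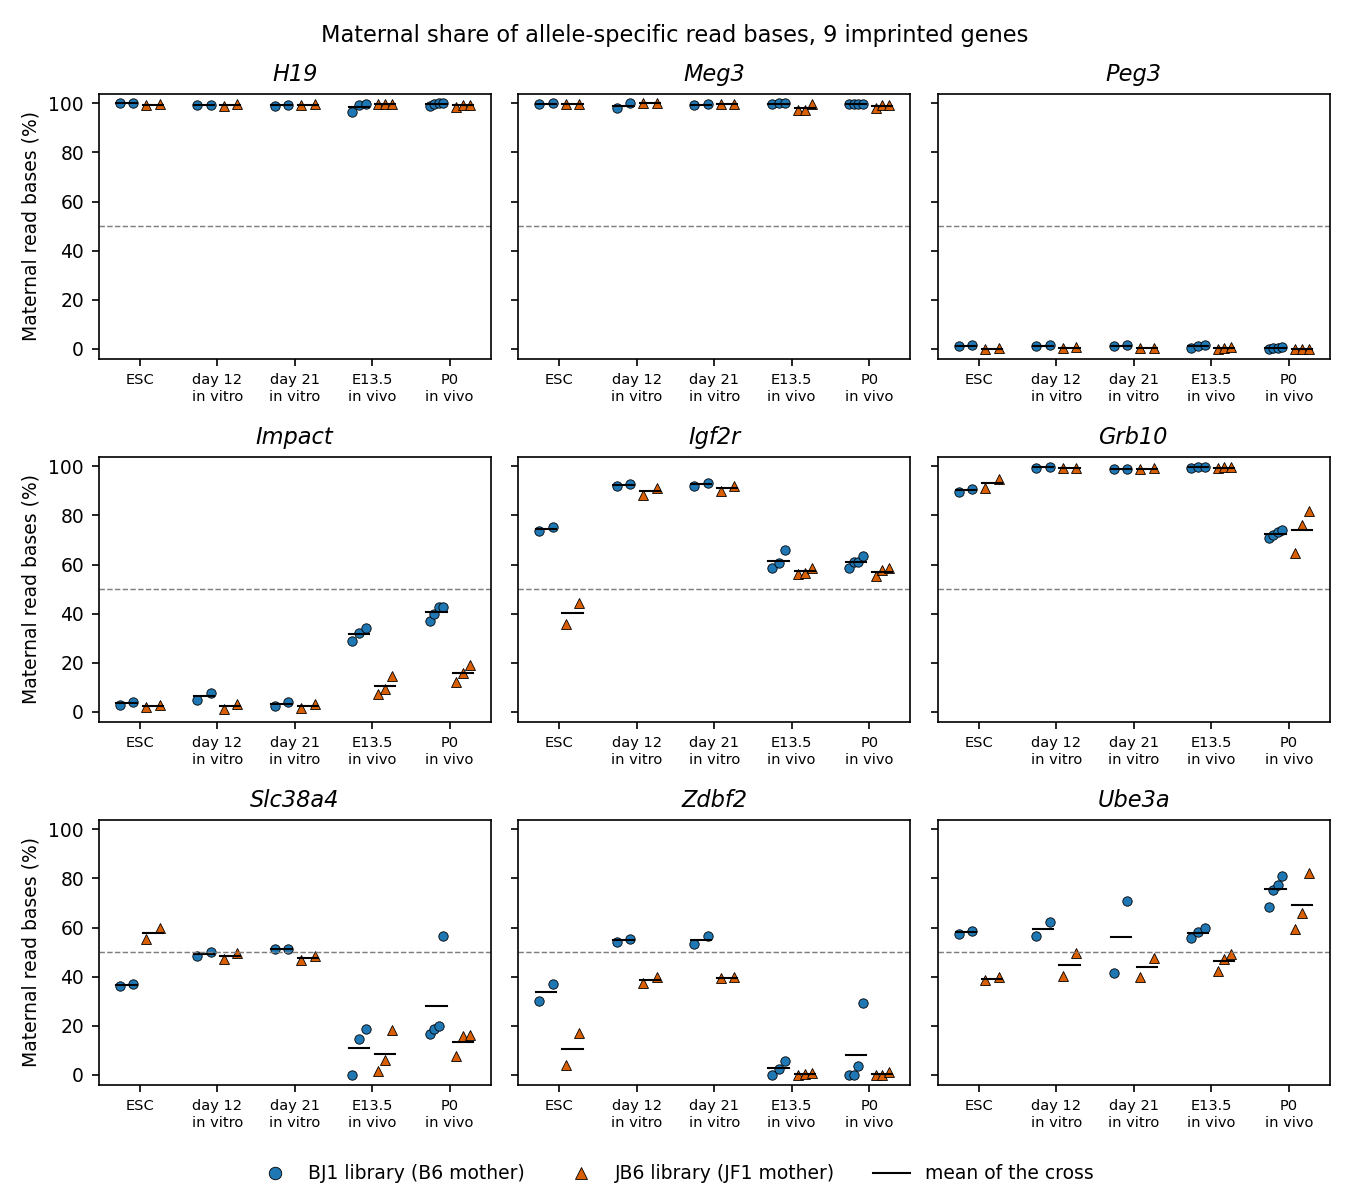
Maternal share of read bases (%, y axis) for 9 genes in ESCs, in vitro day 12 and day 21, and in vivo E13.5 and P0 (x axis). Each point is a library (circles BJ1, triangles JB6), short lines are the mean of a cross, and the dashed line is 50%. Slc38a4 and Zdbf2 lie near 50% at days 12 and 21 and below 22% on average in vivo.

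The same question was asked of the stem cells and their derivatives. Many listed genes were strongly biased, with n = 4 at each stage. H19 was 99.7% ± 0.342 maternal in ESCs and 99.3% ± 0.22 at day 21, and Meg3 was 99.9% ± 0.0819 and 99.6% ± 0.153. Peg3 was 0.682% ± 0.645 maternal in ESCs and 0.874% ± 0.515 at day 12, and Impact was 2.96% ± 0.905 and 4.33% ± 2.78. Igf2r, the receptor that clears IGF2, was 91% ± 1.93 maternal at day 12 and 91.8% ± 1.28 at day 21, and Zim1 was 97.7% ± 1.45 and 98.2% ± 0.948. In ESCs Igf2r differed by cross, at 74.4% ± 1.08 in BJ1 and 40.1% ± 6.26 in JB6 (n = 2 each). Zdbf2 and the amino acid transporter Slc38a4, both on the paternal list, did not pass at day 12, with maternal shares of 46.7% ± 9.39 (adjusted p = 0.812) and 48.9% ± 1.36 (adjusted p = 0.869). Snrpn, a splicing gene of the Prader-Willi domain, was 24.2% ± 3.91 maternal in BJ1 and 0.474% ± 0.67 in JB6 at day 12. Phactr2 was 66% ± 4.5 maternal at day 12 and 64.2% ± 1.67 at day 21, and Klhdc10 (chromosome 6) was 65.6% ± 2.37 at day 12. A large share of the in vitro calls came from one cross. Tubb5, a beta-tubulin gene on chromosome 17, was 96.2% ± 0.709 maternal in JB6 and 51.7% ± 0.413 in BJ1 at day 12, whereas at E13.5 the values were 46% ± 0.355 and 53.7% ± 0.347. Of the 118 maternal calls outside the lists at day 12, 68 were more than 10 points above 50% in JB6 and within 10 points of 50% in BJ1, 39 of them on chromosome 17. Hells (chromosome 19), a chromatin remodeller, had the reverse arrangement, at 98.5% ± 2.05 in BJ1 and 43.8% ± 3.28 in JB6.

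In ESCs 126 of 8991 genes passed (94 maternal, 32 paternal, 690 at an unadjusted p of 0.05), at day 12 188 of 10345 (135, 53 and 804), and at day 21 153 of 11047 (117, 36 and 736). On the maternal list 9 of 22, 16 of 28 and 17 of 28 tested genes passed as maternal, and on the paternal list 13 of 21, 21 of 29 and 22 of 31 as paternal. Of the paternal list, Sfmbt2 in ESCs (74.2% ± 5.13 maternal in BJ1 and 39.6% ± 3.5 in JB6) and Casd1 at day 12 (58.9% ± 4.86) passed as maternal. Both calls were lost with DESeq2 (adjusted p = 0.213 and 0.152) and with limma on log2 ratios (adjusted p = 0.598 and 0.317), and that of Sfmbt2 also without ESC_BJ1 replicate 1 (0.37, adjusted p = 0.128) and without ESC_JB6 replicate 2 (0.37, adjusted p = 0.292). Adjusted over the list alone, 26 of 43, 42 of 57 and 43 of 59 listed genes passed. Outside the lists 150 genes passed at day 12 and 114 at day 21, against 12 at E13.5 and 19 at P0. Counts with at least 10 points the same way in both crosses were 33, 49 and 43, and limma on log2 ratios gave 41, 70 and 59. Leaving out a single library moved the ESC count to 79 (without ESC_BJ1 replicate 2) or 199 (without ESC_JB6 replicate 1), and the day 12 count to 112 (without d12_JB6 replicate 2).

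Overlap between culture and cortex was counted over genes tested at both stages. Day 12 and E13.5 shared 33 genes of 160 and 46 called, all in the same direction, where chance would give 0.39 (Fisher's exact test, one-sided, p = 2.13e-49). Day 21 and P0 shared 33 of 125 and 53 called, again all in the same direction, against 0.32 by chance (Fisher's exact test, p = 7.7e-51). Among genes biased the same way in both crosses the shared numbers were 26 of 35 and 34, and 22 of 34 and 28.

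A further test in the same fit compared the B6 with the JF1 allele. Mapping bias toward the reference strain, or errors in the strain differences, would fall in this term too and were not separated from allele differences. At E13.5 the chromatin protein gene Hmgn2 was read almost wholly from the B6 allele, at 99.98% ± 0.0186 (n = 6), and at P0 Morf4l1 almost wholly from JF1, with a B6 share of 0.307% ± 0.524 (n = 7). Strain differences passed for 4009 genes in ESCs, 3712 at day 12, 3800 at day 21, 4588 at E13.5 and 5012 at P0. The B6 allele was the higher one in 2349, 2122, 2161, 2810 and 3040 of them, respectively. With a separate scaling factor for each allele, JF1 calls outnumbered B6 calls at the 4 stages other than P0, with 2344 against 2248 at E13.5, so the excess of B6 calls at those stages depended on the scaling. DESeq2 gave 2314 calls in ESCs, 1644 at day 12, 1677 at day 21 and 2851 at E13.5.

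The next tests compared parental bias between stages, first along the culture. From ESCs to day 12 Grb10 rose from 91.7% ± 2.34 to 99.5% ± 0.156 maternal (difference of log2 maternal to paternal ratio 4.30 ± 0.375, adjusted p = 5.14e-06), and Igf2r rose by 2.82 ± 0.142, adjusted p = 2.44e-20. Ddc, which makes dopamine and serotonin from their precursors, changed from 60.5% ± 12.6 to 18.1% ± 12.9 maternal, a difference of −3.05 ± 0.45, adjusted p = 2.21e-05. Mirg, a host of microRNAs in the Meg3 domain, changed by −4.03 ± 0.458, adjusted p = 1.13e-07, from 99.7% ± 0.415 to 93.5% ± 3.35. From day 12 to day 21 Inpp5f changed to 14.9% ± 3.18 maternal, from 31.6% ± 12.1 in BJ1 and 51.5% ± 2.66 in JB6, with a difference of −1.95 ± 0.191, adjusted p = 2.79e-09, and the collagen gene Col1a2 by −0.58 ± 0.078, adjusted p = 1.51e-05. At day 12 against ESCs 29 of 8513 genes passed, 18 with a more maternal and 11 with a more paternal share, 8 of them among 43 listed genes, with 13 adjusted over the list alone and 635 genes at an unadjusted p of 0.05. At day 21 against day 12 it was 5 of 10095, 1 more maternal and 4 more paternal, 1 of them among 55 listed genes, with 5 adjusted over the list alone and 569 at an unadjusted p of 0.05. The first count was 18 when only these 2 stages were fitted, and 12 with counts divided by 3. The second fell to 3 without d12_BJ1 replicate 2, d21_BJ1 replicate 2, d21_JB6 replicate 1 or d21_JB6 replicate 2, and to 2 without d12_JB6 replicate 2.

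In cortex, Grb10 had the largest change among the genes that passed between E13.5 and P0, a difference of −6.41 ± 0.271, adjusted p = 1.65e-10, toward a less maternal share at P0. Igf2, a fetal growth factor on the paternal list, went from 15.9% ± 12.4 to 42% ± 10.9 maternal (2.33 ± 0.118, adjusted p = 1.83e-15). The crosses differed at both stages, with 26.25% in BJ1 and 5.65% in JB6 at E13.5, and 50.43% and 30.65% at P0. A pair of genes on chromosome 15 became more maternal: Eif2c2, a component of the RNA silencing machinery, rose from 55.6% ± 1.66 to 69.2% ± 4.08 (0.89 ± 0.09, adjusted p = 1.36e-09), and Trappc9 rose from 58.6% ± 2.07 to 70.4% ± 3.03 (0.76 ± 0.108, adjusted p = 1.04e-05). Ube3a, a ubiquitin ligase whose paternal copy is silenced in neurons, rose from 52.1% ± 6.92 to 72.8% ± 8.44 (1.29 ± 0.238, adjusted p = 0.00254), a call lost with counts divided by 3 (1.27, adjusted p = 0.146) and without P0_JB6 replicate 3 (1.05, adjusted p = 0.0917). Inpp5f became more paternal, with a difference of −0.65 ± 0.092, adjusted p = 1.04e-05. In total 15 of 9564 genes passed, 9 more maternal and 6 more paternal at P0, of which 8 were among 47 listed genes, with 15 adjusted over the list alone and 510 at an unadjusted p of 0.05. The count was 8 without E13.5_BJ1 replicate 1 or P0_JB6 replicate 3, 9 without E13.5_JB6 replicate 2 or P0_JB6 replicate 2, 8 with counts divided by 3, and 7 in female libraries only, a setting chosen after the data were seen.

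The comparison of culture with cortex paired day 12 with E13.5 and day 21 with P0. Zdbf2 was less paternal in culture at both pairs, with differences of 6.42 ± 0.58, adjusted p = 1.93e-06, and of 5.42 ± 0.702, adjusted p = 0.000172. Ndn, another gene of the Prader-Willi domain, was 12.9% ± 9.93 maternal at day 12 and 2.18% ± 3.66 at E13.5 (4.64 ± 0.64, adjusted p = 1.93e-06), and its day 21 to P0 difference was 5.25 ± 0.469, adjusted p = 2.53e-11. The rise lay in BJ1, at 21.4% at day 12 (n = 2) and 0% at E13.5 (n = 3), while JB6 was at 4.41% and 4.36%. Zim1 was 98.2% ± 0.948 maternal at day 21 and 55.7% ± 12.9 at P0, a difference of 5.38 ± 0.31, adjusted p = 5.3e-18. Grb10 was more maternal at day 21 than at P0, by 5.21 ± 0.266, adjusted p = 2.61e-10. Genes of chromosome 17 with the JB6-only bias also passed, among them the ribosomal gene Rps18, which was 99.9% maternal in JB6 and 45.5% in BJ1 at day 12 (n = 2 each, difference from E13.5 4.70 ± 0.069, adjusted p = 5.4e-44). Day 12 against E13.5 gave 84 of 9211 genes, 74 more maternal and 10 more paternal in culture, with 16 among 47 listed genes and 24 adjusted over the list alone. Day 21 against P0 gave 89 of 9686, 78 more maternal and 11 more paternal in culture, with 20 among 50 listed genes and 29 adjusted over the list alone. Counts at an unadjusted p of 0.05 were 732 and 653. With at least 10 points the same way in both crosses, the counts were 11 and 15.

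Summed over alleles, the same read bases give expression levels, and the first contrast followed ESCs to day 12 (n = 4 each). Nanog, a transcription factor of the pluripotent state, fell from 185 ± 45.3 to 0.484 ± 0.619 CPM (log2 −8.66 ± 0.389, adjusted p = 7.54e-16). Of 22 tested pluripotency genes 22 fell (22 passed adjusted over the list alone), with a camera adjusted p = 8.9e-13, and adjusted p = 0.0033 with an estimated correlation. Genes of dorsal telencephalic progenitors rose, among them Sox9 (log2 6.29 ± 0.272, adjusted p = 3.9e-16) and Fabp7 (log2 6.68 ± 0.567), both of radial glia. Of 20 dorsal progenitor genes 18 rose, 1 fell and 1 did not pass (19 passed adjusted over the list alone), with a camera adjusted p = 4e-05, and adjusted p = 0.027 with an estimated correlation. In the group of DNA methylation and imprint maintenance genes the de novo methyltransferase gene Dnmt3b fell (log2 −4.80 ± 0.24, adjusted p = 5.03e-15), Tet1 fell (log2 −4.43 ± 0.351) and Tet3 rose (log2 2.31 ± 0.214). Of the 22 tested in this group 3 rose, 16 fell and 3 did not pass (19 passed adjusted over the list alone), with a camera adjusted p = 0.0031, and adjusted p = 0.24 with an estimated correlation. Of 28 genes on the maternal imprinted list 16 rose, 6 fell and 6 did not pass (22 passed adjusted over the list alone), with a camera adjusted p = 0.025, and adjusted p = 0.24 with an estimated correlation. Of 26 on the paternal list 15 rose, 5 fell and 6 did not pass (20 passed adjusted over the list alone), with a camera adjusted p = 0.025, and adjusted p = 0.24 with an estimated correlation. Dlk1, a paternally expressed Notch ligand relative, rose from 1.52 ± 0.93 to 200 ± 26.4 CPM. Of 18 mesendoderm and other lineage genes 13 rose, 4 fell and 1 did not pass (17 passed adjusted over the list alone), with a camera adjusted p = 0.019, and adjusted p = 0.24 with an estimated correlation. Of 15 vascular, blood, meningeal and microglial genes 13 rose, 1 fell and 1 did not pass (14 passed adjusted over the list alone), with a camera adjusted p = 0.0016, and adjusted p = 0.24 with an estimated correlation. The collagen gene Col3a1 was at 1610 ± 324 against 5.51 ± 4.36 CPM. One library stood apart in these groups: ESC_JB6 replicate 2 held H19 at 745 CPM against 16.2, 17.6 and 29.5 in the other ESC libraries, and Krt8, an epithelial keratin, at 571 against 10.7 to 20. Its Nanog level was 125 CPM against 175 to 223. Of 24 cell cycle genes 17 fell and 7 did not pass (15 passed adjusted over the list alone), with a camera adjusted p = 0.0006, and adjusted p = 0.24 with an estimated correlation. Of 16 stress genes 10 rose and 6 fell (16 passed adjusted over the list alone), with a camera adjusted p = 0.51. Of 5 caudal neural tube genes 3 rose and 2 fell (5 passed adjusted over the list alone), with a camera adjusted p = 0.64. Of 17 cortical neuron genes 11 rose, 3 fell and 3 did not pass (14 passed adjusted over the list alone), with a camera adjusted p = 0.025, and adjusted p = 0.24 with an estimated correlation. Of 5 ventral forebrain and GABAergic genes 4 rose and 1 did not pass (4 passed adjusted over the list alone), with a camera adjusted p = 0.032, and adjusted p = 0.24 with an estimated correlation. Of 9 glial genes 4 rose, 2 fell and 3 did not pass (6 passed adjusted over the list alone), with a camera adjusted p = 0.55. In total 8102 of 10484 genes passed, 4213 higher and 3889 lower at day 12, and 3982 passed against a minimum change of 2-fold.

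Day 21 was then compared with day 12 (n = 4 each). Cell cycle genes fell together, including the topoisomerase gene Top2a, from 365 ± 99.7 to 80.5 ± 18 CPM (log2 −2.14 ± 0.212, adjusted p = 1.01e-08), and Ccnb1 (log2 −2.11 ± 0.164). Among 24 cell cycle genes 24 fell (24 passed adjusted over the list alone), with a camera adjusted p = 5.1e-18, and adjusted p = 0.026 with an estimated correlation. Neuronal genes rose, with the microtubule-binding gene Mapt at 919 ± 122 against 66.1 ± 27.9 (log2 3.93 ± 0.272, adjusted p = 3.86e-11) and the synaptic vesicle gene Syt1 at log2 3.75 ± 0.321. Of 24 cortical neuron genes 16 rose, 2 fell and 6 did not pass (20 passed adjusted over the list alone), with a camera adjusted p = 0.00027, and adjusted p = 0.21 with an estimated correlation. Gfap, the intermediate filament of astrocytes, rose from 0.79 ± 0.166 to 217 ± 166 (log2 7.86 ± 0.409). Of 15 glial genes 9 rose and 6 did not pass (9 passed adjusted over the list alone), with a camera adjusted p = 0.0078, and adjusted p = 0.21 with an estimated correlation. Among ventral forebrain and GABAergic genes Gad1, which makes GABA, rose (log2 3.03 ± 0.404). Of 9 genes in this group 3 rose, 3 fell and 3 did not pass (7 passed adjusted over the list alone), with a camera adjusted p = 0.91. Col1a2 rose (log2 3.52 ± 0.549). Of 16 vascular, blood, meningeal and microglial genes 10 rose, 1 fell and 5 did not pass (11 passed adjusted over the list alone), with a camera adjusted p = 0.036, and adjusted p = 0.6 with an estimated correlation. Hells fell (log2 −2.23 ± 0.345). Of 20 DNA methylation and imprint maintenance genes 1 rose, 8 fell and 11 did not pass (9 passed adjusted over the list alone), with a camera adjusted p = 0.014, and adjusted p = 0.47 with an estimated correlation. Of 21 dorsal progenitor genes 3 rose, 4 fell and 14 did not pass (7 passed adjusted over the list alone), with a camera adjusted p = 0.37. Hes5, a target of Notch, fell (log2 −2.07 ± 0.344). Outside the lists Igdcc3 fell from 617 to 29.5 CPM (log2 −4.30 ± 0.206). Of 29 genes on the maternal imprinted list 7 rose, 6 fell and 16 did not pass (13 passed adjusted over the list alone), with a camera adjusted p = 0.84. Of 29 on the paternal list 8 rose, 4 fell and 17 did not pass (12 passed adjusted over the list alone), with a camera adjusted p = 0.59. Of 18 mesendoderm and other lineage genes 1 rose, 5 fell and 12 did not pass (3 passed adjusted over the list alone), with a camera adjusted p = 0.59. Of 16 stress genes 2 rose, 3 fell and 11 did not pass (4 passed adjusted over the list alone), with a camera adjusted p = 0.84. Of 9 pluripotency genes 1 rose, 3 fell and 5 did not pass (4 passed adjusted over the list alone), with a camera adjusted p = 0.25. Of 7 caudal neural tube genes 1 rose, 2 fell and 4 did not pass (3 passed adjusted over the list alone), with a camera adjusted p = 0.31. In total 5751 of 11255 genes passed, 3361 higher and 2390 lower at day 21, and 1241 passed against a minimum change of 2-fold.

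In cortex the matching interval was P0 against E13.5 (n = 7 and 6). Mki67, a marker of dividing cells, fell from 732 ± 116 to 30.2 ± 9.42 CPM (log2 −4.55 ± 0.315, adjusted p = 5.52e-12). Of 24 cell cycle genes 24 fell (24 passed adjusted over the list alone), with a camera adjusted p = 3e-16, and adjusted p = 0.022 with an estimated correlation. Dorsal progenitor genes fell with it, among them Neurog2 (log2 −4.91 ± 0.257) and Eomes (log2 −3.49 ± 0.191), transcription factors of neurogenic progenitors. Of 25 dorsal progenitor genes 2 rose, 20 fell and 3 did not pass (22 passed adjusted over the list alone), with a camera adjusted p = 4.4e-06, and adjusted p = 0.022 with an estimated correlation. Neuronal genes rose, with Mapt at 5600 ± 208 against 326 ± 106, log2 4.17 ± 0.216 and the calmodulin-dependent kinase gene Camk2b at log2 4.90 ± 0.186. Of 31 cortical neuron genes 22 rose, 5 fell and 4 did not pass (28 passed adjusted over the list alone), with a camera adjusted p = 0.0013, and adjusted p = 0.36 with an estimated correlation. Glial genes rose, including Gfap (log2 7.74 ± 0.359) and Olig1 (log2 7.72 ± 0.374, adjusted p = 2.93e-15), a factor of the oligodendrocyte lineage. Of 15 glial genes 13 rose, 1 fell and 1 did not pass (14 passed adjusted over the list alone), with a camera adjusted p = 0.00044, and adjusted p = 0.057 with an estimated correlation. The interneuron genes Npy (log2 6.11 ± 0.259) and Lhx6 (log2 3.82 ± 0.274) rose. Of 13 ventral forebrain and GABAergic genes 9 rose, 2 fell and 2 did not pass (11 passed adjusted over the list alone), with a camera adjusted p = 0.021, and adjusted p = 0.49 with an estimated correlation. Imprinted genes moved both ways, as Meg3 rose (2110 ± 264 against 93.6 ± 31.5 CPM) while Grb10 fell (52.3 ± 10.2 against 551 ± 110). Of 24 genes on the maternal list 10 rose, 11 fell and 3 did not pass (21 passed adjusted over the list alone), with a camera adjusted p = 0.96. Of 28 on the paternal list 11 rose, 6 fell and 11 did not pass (17 passed adjusted over the list alone), with a camera adjusted p = 0.52. The mean log2 fold of the maternal list was 0.35 and its median −0.25. Of 20 DNA methylation and imprint maintenance genes 2 rose, 11 fell and 7 did not pass (13 passed adjusted over the list alone), with a camera adjusted p = 0.091. Blood RNA differed among the E13.5 libraries, with the embryonic globin gene Hbb-y at 728 to 6020 CPM, and E13.5_BJ1 replicate 2 was lowest in Hbb-y, in H19 (24.4 to 283) and in Igf2 (5.95 to 124). Of 17 vascular, blood, meningeal and microglial genes 7 rose, 4 fell and 6 did not pass (11 passed adjusted over the list alone), with a camera adjusted p = 0.96. Of 13 stress genes 3 rose, 8 fell and 2 did not pass (11 passed adjusted over the list alone), with a camera adjusted p = 0.36. Of 8 mesendoderm and other lineage genes 1 rose, 2 fell and 5 did not pass (3 passed adjusted over the list alone), with a camera adjusted p = 0.93. Of 4 pluripotency genes 2 rose, 1 fell and 1 did not pass (3 passed adjusted over the list alone), with a camera adjusted p = 0.96. The 1 tested caudal neural tube gene was lower. In total 8193 of 10877 genes passed, 4138 higher and 4055 lower at P0, and 3137 passed against a minimum change of 2-fold.

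**Figure D3:**
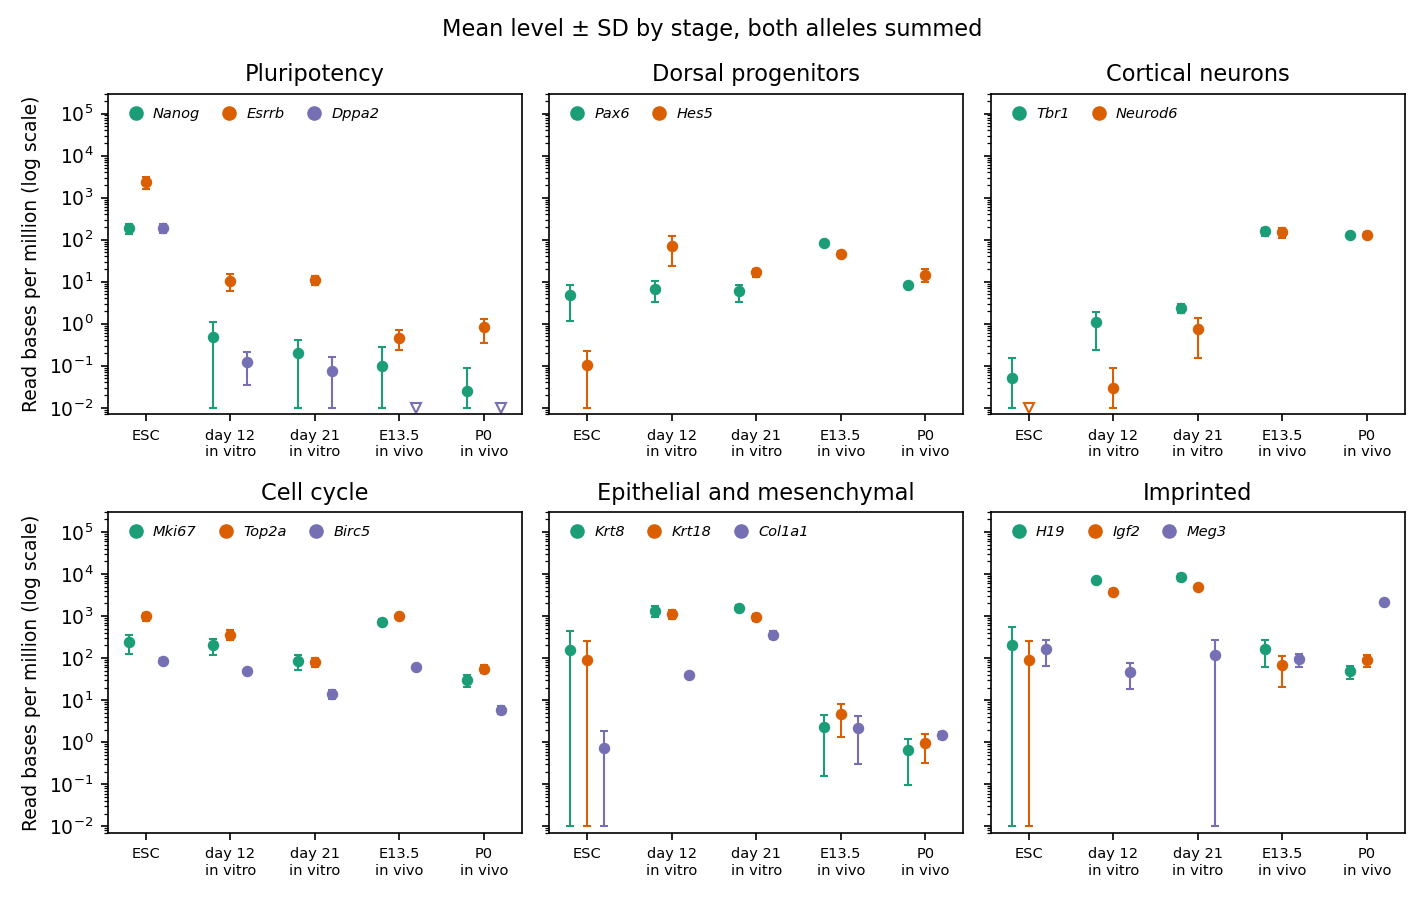
Level of 16 genes in CPM of read bases (y axis, log scale) at the 5 stages (x axis), in 6 panels. Points are means with SD bars, lower bars are drawn to no less than 0.01, and an open triangle at 0.01 marks a mean of 0. Tbr1 averages 1.09 at day 12 against 157 at E13.5.

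Day 12 cultures were set beside E13.5 cortex (n = 4 and 6). Lhx2 was at 3.78 ± 1.41 against 185 ± 21.7 CPM (log2 −5.59 ± 0.286, adjusted p = 8.06e-15) and Emx1 was lower as well (log2 −5.39 ± 0.229), both transcription factors of dorsal progenitors. Of 25 dorsal progenitor genes 2 were higher, 19 were lower and 4 did not pass (22 passed adjusted over the list alone), with a camera adjusted p = 0.00025, and adjusted p = 0.061 with an estimated correlation. Cortical neuron genes were lower in culture, with Tbr1 at 1.09 ± 0.851 against 157 ± 32.2, log2 −7.15 ± 0.233. Of 29 cortical neuron genes 1 was higher, 27 were lower and 1 did not pass (28 passed adjusted over the list alone), with a camera adjusted p = 1.3e-07, and adjusted p = 0.061 with an estimated correlation. The epithelial keratin genes Krt8 (1340 ± 380 against 2.32 ± 2.16) and Krt18 (1140 ± 282 against 4.77 ± 3.43) were higher. Of 15 mesendoderm and other lineage genes 13 were higher, 1 was lower and 1 did not pass (14 passed adjusted over the list alone), with a camera adjusted p = 0.00042, and adjusted p = 0.17 with an estimated correlation. Gata4, on the same list, was at 48.9 ± 19.7 CPM at day 12, but had no read base at E13.5 and was not tested. Among stress genes the p53 target Cdkn1a was higher (log2 4.66 ± 0.248, adjusted p = 2.66e-14). Of 16 stress genes 14 were higher and 2 were lower (16 passed adjusted over the list alone), with a camera adjusted p = 0.00049, and adjusted p = 0.061 with an estimated correlation. H19 was higher in culture (7150 ± 1100 against 167 ± 107). Of 26 genes on the maternal imprinted list 17 were higher, 4 were lower and 5 did not pass (21 passed adjusted over the list alone), with a camera adjusted p = 0.0086, and adjusted p = 0.061 with an estimated correlation. Of 29 on the paternal list 11 were higher, 10 were lower and 8 did not pass (21 passed adjusted over the list alone), with a camera adjusted p = 0.53. Dlk1 was among the higher (log2 6.23 ± 0.45) and Peg13 among the lower (log2 −2.93 ± 0.185). Of 6 pluripotency genes 5 were higher and 1 was lower (6 passed adjusted over the list alone), with a camera adjusted p = 0.035, and adjusted p = 0.11 with an estimated correlation. The orphan receptor gene Esrrb was higher in culture (log2 4.40 ± 0.399). The globin gene Hbb-y was lower in culture (log2 −9.05 ± 0.465). Of 18 vascular, blood, meningeal and microglial genes 7 were higher, 5 were lower and 6 did not pass (12 passed adjusted over the list alone), with a camera adjusted p = 0.73. The median log2 fold of that list was 0.11 and its mean −0.13. Hoxb2 (37 ± 5.2 against 0.0751 ± 0.184) and Wnt1 (38.3 ± 24.3 against 0.0681 ± 0.11), genes of the caudal neural tube, were higher in culture. Of 3 caudal neural tube genes 2 were higher and 1 did not pass (3 passed adjusted over the list alone), with a camera adjusted p = 0.051. Hoxb3, on the same list, was at 10.5 ± 3.83 CPM at day 12, but had no read base at E13.5 and was not tested. Of 24 cell cycle genes 4 were higher, 13 were lower and 7 did not pass (17 passed adjusted over the list alone), with a camera adjusted p = 0.11. Of 20 DNA methylation and imprint maintenance genes 4 were higher, 14 were lower and 2 did not pass (18 passed adjusted over the list alone), with a camera adjusted p = 0.1. Of 11 ventral forebrain and GABAergic genes 2 were higher, 7 were lower and 2 did not pass (9 passed adjusted over the list alone), with a camera adjusted p = 0.28. Of 8 glial genes 5 were higher and 3 were lower (8 passed adjusted over the list alone), with a camera adjusted p = 0.7. In total 8689 of 10930 genes passed, 4075 higher and 4614 lower in culture, and 3944 passed against a minimum change of 2-fold.

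Day 21 cultures were set beside P0 cortex (n = 4 and 7). Mef2c, a transcription factor of cortical neurons, was at 4.63 ± 2.93 against 404 ± 26.1 CPM (log2 −6.41 ± 0.266, adjusted p = 5.72e-17). Of 30 cortical neuron genes 29 were lower and 1 did not pass (29 passed adjusted over the list alone), with a camera adjusted p = 3.3e-10, and adjusted p = 0.062 with an estimated correlation. Lhx2 was lower in culture (log2 −4.16 ± 0.279) while Hes1 (log2 3.38 ± 0.233) and the filament gene Vim (log2 2.82 ± 0.141) were higher. Of 24 dorsal progenitor genes 11 were higher, 9 were lower and 4 did not pass (20 passed adjusted over the list alone), with a camera adjusted p = 0.97. The median log2 fold of that list was 0.35 and its mean −0.55. Interneuron genes were lower, with Npy at log2 −5.35 ± 0.295 and Dlx1 at log2 −3.72 ± 0.483. Of 13 ventral forebrain and GABAergic genes 11 were lower and 2 did not pass (11 passed adjusted over the list alone), with a camera adjusted p = 0.0048, and adjusted p = 0.28 with an estimated correlation. Cell cycle genes were higher in culture, among them Plk1 (log2 2.40 ± 0.159) and Mcm3 (log2 2.24 ± 0.118). Of 24 cell cycle genes 23 were higher and 1 did not pass (23 passed adjusted over the list alone), with a camera adjusted p = 2.3e-05, and adjusted p = 0.26 with an estimated correlation. The epithelial keratin gene Krt8 was higher (log2 11.43 ± 1.004). Of 12 mesendoderm and other lineage genes 11 were higher and 1 was lower (12 passed adjusted over the list alone), with a camera adjusted p = 0.00097, and adjusted p = 0.28 with an estimated correlation. The collagen gene Col3a1 was at 7120 ± 1360 against 66.1 ± 21.7 CPM. Of 18 vascular, blood, meningeal and microglial genes 11 were higher, 3 were lower and 4 did not pass (14 passed adjusted over the list alone), with a camera adjusted p = 0.25. Of 16 stress genes 14 were higher, 1 was lower and 1 did not pass (15 passed adjusted over the list alone), with a camera adjusted p = 0.00017, and adjusted p = 0.062 with an estimated correlation. Trib3, induced by the unfolded protein response, was higher in culture (log2 6.37 ± 0.346, adjusted p = 1.08e-14). H19 was higher (8450 ± 1560 against 48.4 ± 16) and Meg3 lower (122 ± 154 against 2110 ± 264). Of 26 genes on the maternal imprinted list 15 were higher, 3 were lower and 8 did not pass (18 passed adjusted over the list alone), with a camera adjusted p = 0.019, and adjusted p = 0.25 with an estimated correlation. Of 30 on the paternal list 14 were higher, 11 were lower and 5 did not pass (25 passed adjusted over the list alone), with a camera adjusted p = 0.65. Of 16 glial genes 5 were higher, 8 were lower and 3 did not pass (13 passed adjusted over the list alone), with a camera adjusted p = 0.25. Of 20 DNA methylation and imprint maintenance genes 4 were higher, 11 were lower and 5 did not pass (15 passed adjusted over the list alone), with a camera adjusted p = 0.25. Of 7 pluripotency genes 5 were higher and 2 were lower (7 passed adjusted over the list alone), with a camera adjusted p = 0.25. The 1 tested caudal neural tube gene was higher. Hoxb2, on the same list, was at 19.1 ± 6.66 CPM at day 21, but had no read base at P0 and was not tested. In total 9305 of 11529 genes passed, 4655 higher and 4650 lower in culture, and 4717 passed against a minimum change of 2-fold. For each gene given a fold in the 5 contrasts, every library of one stage lay above every library of the other.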

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

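All tests of causes and all regroupings of libraries in this part were chosen after the results were seen.

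The first pattern is a set of genes that were more than 10 points above 50% maternal in JB6 and within 10 points of 50% in BJ1 at in vitro day 12, 68 of 118 maternal calls outside the lists, with 39 on chromosome 17 and 8 on chromosome 4. Some lay near that bound in BJ1, as Jmjd5 at 59.6% against 62.6% in JB6 and H2-D1 at 59.4%, so not all are balanced there. Their median JB6 maternal share was 76.6% in ESCs, 75.4% at day 12 and 74.2% at day 21. Mapping or strain-difference bias is argued against by the median of 49.2% in JB6 at E13.5. Loss of the paternal copy in the set as a whole is argued against by total levels, JB6 over BJ1, day 12 minus E13.5, with a median log2 of −0.16 (quartiles −0.36 and 0.14). That lies a median of 0.58 (quartiles 0.16 and 0.85) above the level that loss of the missing paternal reads would leave, while 9 of the 68 genes lay at or below it and stay open. Non-B6 sequence in the B6 parent of the JB6 line is a candidate explanation: 34 genes had a neighbouring tested gene in the set, against at most 10 in 10000 random sets. With 39 genes on chromosome 17 neighbours were likely, and any cause that acts on stretches of genes would give them. The count therefore does not single out non-B6 sequence. Biological causes were not tested, and line and cross are confounded in vitro because each cross has 1 line.

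The second pattern is maternal reads from the Snrpn domain in BJ1 in vitro, with a domain mean of 24% in ESCs, 25.6% at day 12 and 22.7% at day 21 (n = 2 each), against 2.45%, 2.39% and 1.84% in JB6. To weigh RNA of the other cross as the whole source, 16 paternal-list genes outside the domain that passed as paternal at day 12 were read. Their median was 3.26% maternal in BJ1 (quartiles 1.21% and 16.9%). Passing as paternal itself asks for a low maternal share, so this median cannot decide. Listed genes that did not pass were left out, as Zdbf2 at 54.7% and Slc38a4 at 49.3% in BJ1. Some of the 16 were high, with Igf2 at 34.1%, Inpp5f at 31.6%, Dlk1 at 24.8%, Zrsr1 at 17.7% and Airn at 16.7%. Pooled over the 16 genes the BJ1 share was 20.6% at day 12 and 20.7% at day 21, near that of the domain, with Igf2 the most abundant (23900 read bases per library at day 12). The next, Nnat, Peg10 and Peg3, were at 0.981%, 0.241% and 1.29%, and in ESCs the pooled share was 4.82% against 24% for the domain. RNA of the other cross would add maternal reads to Nnat, Peg10 and Peg3 as well, so these genes argue against it as the whole source. An effect of the cross in any tissue is argued against by 0.274% in BJ1 at E13.5. B6-like sequence on the paternal copy that reaches past the domain is argued against by a median of 52.7% for the 10 nearest tested genes. Those genes lie outside the domain, so they cannot decide about a stretch confined to it, which stays open. Partial maternal expression in this line may remain, as an untested hypothesis.

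The third pattern is the lower maternal share of Grb10 at P0 than at E13.5. Maternal Grb10 fell from 549 ± 110 (n = 6) to 38.3 ± 8.06 (n = 7) CPM, and paternal Grb10 rose from 2.39 ± 1.28 to 14 ± 4.33, by 11.6 (exact two-sided permutation test over 1716 regroupings, p = 0.000583, the smallest they can give), which argues against loss of maternal transcripts alone. RNA of the other cross is argued against by all 5 other maternal-list genes tested at both stages and over 90% maternal at E13.5, the lowest at P0 being Rian at 96.7%, and a strain difference by a BJ1 minus JB6 difference of −1.76 points. Age and cell makeup differ between the stages, stay open and were not tested, so a change in cell makeup is an untested hypothesis.

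Differences in parental bias between stages numbered 29 genes at day 12 against ESCs, 5 at day 21 against day 12, 15 at P0 against E13.5, 84 at day 12 against E13.5 and 89 at day 21 against P0. In fits of 2 stages alone, the libraries were also split anew between the stages, in all possible ways up to 100 and otherwise in 100 splits, those beside the real one drawn at random. Splits that left a stage without 1 of the crosses were not fitted, and the counts of splits below include the real one. At day 12 against ESCs the real split gave 18 genes and 2 of 34 splits as many (highest other 1648, next 1), and at day 21 against day 12 4 genes and 2 of 34 (230, next 1). At P0 against E13.5 it gave 14 genes and 5 of 100 (738, next 711), at day 12 against E13.5 91 genes and 5 of 94 (492, next 478), and at day 21 against P0 98 genes and 4 of 90 (614, next 254). In each contrast the split with the highest count exchanged stages between the crosses, wholly or for most libraries, which puts differences in strain bias between stages into the parental contrast and points to structure of the samples. These counts of splits therefore say nothing about chance. A further set kept the splits whose libraries of each stage were shared nearly alike between the crosses, with a carry-over of strain bias of at most 0.25, where a full exchange has 2. At P0 against E13.5 only the real split of this kind gave as many genes (14 genes, 1 of 100 splits, highest other 3). The same held at day 12 against E13.5 (91 genes, 1 of 58, highest other 0) and at day 21 against P0 (98 genes, 1 of 100, highest other 0). Splits that mix stages also widen the fitted spread, which lowers their counts, so this ranking does not exclude chance. At day 12 against ESCs and at day 21 against day 12 the 17 splits of this kind are too few for a share under 0.05, with 18 and 4 genes and 0 as the highest other. For parental bias at P0 only the real grouping gave as many genes, with 57 genes, 1 of 35 regroupings and 2 as the highest other. At E13.5 the 10 possible regroupings are too few for a share under 0.05, with 49 genes and 1 as the highest other. In each expression contrast only the real grouping gave as many genes. It gave 7065 at day 12 against ESCs (35 regroupings, highest other 0) and 5375 at day 21 against day 12 (35, 1). It gave 8866 at P0 against E13.5 (100, 8148), 8774 at day 12 against E13.5 (100, 3629) and 9655 at day 21 against P0 (100, 0). Mixed groupings widen the fitted spread here too, so these rankings do not exclude chance either.

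The following genes differed between stages, given as the difference of log2 maternal to paternal ratio ± standard error, first stage minus second. Day 12 minus ESCs gave Asb4 5.01 ± 0.972, Grb10 4.30 ± 0.375, Mirg −4.03 ± 0.458, Ddc −3.05 ± 0.45, Igf2r 2.82 ± 0.142, Cdkn1c 2.55 ± 0.454, Dusp27 1.76 ± 0.317, Pm20d2 −1.27 ± 0.289, Dab2 1.16 ± 0.269 and Plxdc2 −1.10 ± 0.251. The calls were lost without 1 library for Cdkn1c (without ESC_BJ1 replicate 2, 2.42, adjusted p = 0.228), Asb4 (without ESC_JB6 replicate 2, 4.79, adjusted p = 0.114) and Dusp27 (without d12_BJ1 replicate 1, 1.41, adjusted p = 0.242, and without d12_JB6 replicate 2, 1.64, adjusted p = 0.127). Pm20d2 lost its call without ESC_BJ1 replicate 1 (−1.16), d12_BJ1 replicate 1 (−1.31), d12_BJ1 replicate 2 (−1.24) or d12_JB6 replicate 2 (−1.07). Dab2 lost its call without ESC_BJ1 replicate 1 (0.70), d12_BJ1 replicate 2 (1.14), ESC_JB6 replicate 2 (0.31), d12_JB6 replicate 1 (1.16) or d12_JB6 replicate 2 (1.17). Plxdc2 lost its call without ESC_BJ1 replicate 1 (−1.20), ESC_BJ1 replicate 2 (−0.99), d12_BJ1 replicate 2 (−1.11), ESC_JB6 replicate 2 (−0.95) or d12_JB6 replicate 1 (−1.05). The Asb4 value was fitted against no maternal read base in JB6 ESCs, and the change of Plxdc2 lay mainly in BJ1. The crosses moved in opposite directions for Dab2, from 11.85% to 49.8% in BJ1 and from 67.7% to 48.4% in JB6, and for Pm20d2, from 58.6% to 13.6% and from 46.3% to 54.9%. Day 21 minus day 12 gave Inpp5f −1.95 ± 0.191, Poli −0.82 ± 0.152, Col1a2 −0.58 ± 0.078, Klhdc10 −0.46 ± 0.087 and Atp6v0e2 0.36 ± 0.073. Poli lost its call without d12_BJ1 replicate 2 (−0.80), d21_BJ1 replicate 1 (−0.79), d12_JB6 replicate 2 (−0.75) or d21_JB6 replicate 1 (−0.72). Klhdc10 lost its call without d12_BJ1 replicate 1 (−0.42), d21_BJ1 replicate 2 (−0.42), d12_JB6 replicate 2 (−0.46) or d21_JB6 replicate 2 (−0.41). Atp6v0e2 lost its call without d12_BJ1 replicate 2 (0.30), d21_BJ1 replicate 2 (0.33), d12_JB6 replicate 2 (0.29), d21_JB6 replicate 1 (0.35) or d21_JB6 replicate 2 (0.37). P0 minus E13.5 gave Grb10 −6.41 ± 0.271, Igf2 2.33 ± 0.118, Rian 1.77 ± 0.212, Ube3a 1.29 ± 0.238, Eif2c2 0.89 ± 0.09, Crym 0.82 ± 0.189, Trappc9 0.76 ± 0.108, Plk3 0.76 ± 0.172, Inpp5f −0.65 ± 0.092 and Hivep2 −0.62 ± 0.133. Ube3a lost its call without P0_JB6 replicate 3 (1.05). Crym lost its call without E13.5_BJ1 replicate 1 (0.88), E13.5_BJ1 replicate 2 (0.67), E13.5_JB6 replicate 1 (0.66), E13.5_JB6 replicate 2 (0.67), P0_BJ1 replicate 1 (0.81), P0_BJ1 replicate 2 (0.83), P0_BJ1 replicate 3 (0.81), P0_BJ1 replicate 4 (0.82), P0_JB6 replicate 1 (0.82), P0_JB6 replicate 2 (0.84) or P0_JB6 replicate 3 (0.80). Plk3 lost its call without E13.5_BJ1 replicate 1 (0.77), E13.5_BJ1 replicate 2 (0.74), E13.5_BJ1 replicate 3 (0.76), E13.5_JB6 replicate 2 (0.78), E13.5_JB6 replicate 3 (0.63), P0_BJ1 replicate 1 (0.75), P0_BJ1 replicate 2 (0.73), P0_BJ1 replicate 3 (0.74), P0_JB6 replicate 2 (0.72) or P0_JB6 replicate 3 (0.75). Hivep2 lost its call without E13.5_BJ1 replicate 1 (−0.64), E13.5_BJ1 replicate 3 (−0.54), E13.5_JB6 replicate 1 (−0.61), E13.5_JB6 replicate 2 (−0.63) or E13.5_JB6 replicate 3 (−0.64). The change of Crym lay in JB6, from 18.9% at E13.5 to 50.3%, while BJ1 went from 57.7% to 51.3%. Day 12 minus E13.5 gave Zdbf2 6.42 ± 0.58, Peg12 6.21 ± 0.915, Zbtb22 5.22 ± 0.381, Stk19 5.10 ± 0.382, Rxrb 5.10 ± 0.381, Pbx2 4.79 ± 0.538, Rps18 4.70 ± 0.069, Wasf2 4.66 ± 0.564, Kifc1 4.65 ± 0.369 and Ndn 4.64 ± 0.64. The Peg12 value was fitted against no maternal read base at E13.5 and is no bound. The values of Zbtb22, Stk19, Rxrb, Pbx2 and Wasf2 rest mainly on JB6, with no paternal read base there at day 12, and are no bounds, while BJ1 was at 50.9%, 58.1%, 48.5%, 40.9% and 40.9% maternal. Those of Rps18 and Kifc1 also rest mainly on JB6, at 99.9% and 99.3%, and that of Ndn on BJ1, with no maternal read base there at E13.5. Day 21 minus P0 gave Snrpn 5.57 ± 1.247, Zdbf2 5.42 ± 0.702, Zim1 5.38 ± 0.31, Ndn 5.25 ± 0.469, Grb10 5.21 ± 0.266, Bag6 5.13 ± 0.463, 2310061I04Rik 5.11 ± 0.382, Stk19 5.08 ± 0.385, Wasf2 5.02 ± 0.582 and Erp44 4.88 ± 0.481. The Snrpn call was lost without d21_JB6 replicate 2 (4.05, adjusted p = 1). The values of Snrpn and Ndn rest on BJ1, with no maternal read base there at P0, and those of Bag6, 2310061I04Rik, Stk19, Wasf2 and Erp44 mainly on JB6, with no paternal read base there at day 21.

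In P0_BJ1, the group of 4 libraries that could be tested for a library far from the others by Dixon's ratio, 9 of 46 measures lay beyond its 95% limit. The nominal rate of 1 in 20, or 2.3 of 46, assumes continuous values from like libraries. It does not hold here, because the X-linked share follows sex and Mest, Mkrn3 and D7Ertd715e rest on 1 read base each. No excess can therefore be read from the count. Replicate 1 held 7115866 read bases against 5568218 to 5683362 in the others. X-linked maternal share was 98.8% (Wilson interval 98.8% to 98.9%) in replicate 2, the library labelled male, against 58.7% to 63% in the others. Eif2c2 was 64.8% maternal (60.8% to 68.7%) in replicate 1 against 67.2% to 67.7%, and Rian 99.8% (99.7% to 99.9%) in replicate 1 against 99.88% to 99.9%. Slc38a4 was 56.5% maternal (36.8% to 74.4%) in replicate 2 against 16.7% to 20%, and Igsf3 56.2% (53.9% to 58.5%) in replicate 4 against 51% to 51.5%. Mest was 4.17% maternal (0.739% to 20.2%, 1 of 24 read bases) in replicate 2, with 0 of 66 in the others, which allows up to 4.55%. Limits for counts of 0, here and in the next sentences, are approximate and are not Wilson limits. Mkrn3 was 2.56% (0.454% to 13.2%, 1 of 39) in replicate 4, with 0 of 127 in the others, which allows up to 2.36%. D7Ertd715e was 1.79% (0.316% to 9.45%, 1 of 56) in replicate 1, with 0 of 204 in the others, which allows up to 1.47%.

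Mitochondrial genes, tested for expression but not for parental bias, held 668140 paternal-labelled read bases of 25958824, or 2.57% (exact binomial interval 2.57% to 2.58%, counting error only), although the mitochondrial genome comes from the mother. The share was 0.213% in BJ1 and 4.91% in JB6 libraries.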

How the results depend on the processing

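Counting only genes biased by at least 10 points the same way in both crosses, and using female libraries only, were chosen after the results were seen, and the other alternatives were planned. No named gene result reversed its direction in the alternatives that were run. With a separate scaling factor for each allele, the excess of B6 over JF1 strain calls became an excess of JF1 calls in ESCs (1945 against 2008), at day 12 (1807 and 1903), at day 21 (1851 and 1925) and at E13.5 (2248 and 2344), while at P0 B6 stayed ahead (2592 and 2418). Of 223 named parental results, 61 lost their call in at least 1 alternative, as did 14 of 45 named differences, 91 of 425 expression results and 0 of 30 strain results. Leaving out a library ended 27 of the parental, 14 of the difference and 32 of the expression calls.

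Parental calls in ESCs numbered 75 with DESeq2, 41 with limma on log2 ratios and 33 the same way in both crosses. At day 12 they numbered 92, 70 and 49, and 117 with counts divided by 3. At day 21 they numbered 98, 59 and 43, and at P0 the same-way count was 32. Strain calls numbered 2314 with DESeq2 and 2633 with limma in ESCs, 1644 and 1743 at day 12 with 2468 for counts divided by 3, 1677 and 1917 at day 21, and 2851 with DESeq2 at E13.5. Listed imprinted genes in their listed direction at day 12 dropped to 24 with a mean of at least 100 read bases, where fewer genes were tested. Differences between day 12 and ESCs numbered 12 with counts divided by 3, 18 when only 2 stages were fitted and 3 the same way in both crosses. Between day 21 and day 12 they numbered 2 with counts divided by 3 and 2 the same way. Between P0 and E13.5 they numbered 8 with counts divided by 3, 9 with a block for replicate number, 7 in female libraries only and 5 the same way. Same-way differences numbered 11 between day 12 and E13.5, and 15 between day 21 and P0. Against a minimum change of 2-fold the expression counts were 3982, 1241, 3137, 3944 and 4717 in the order of the contrasts above, as that test asks for larger changes. The median gene put the X-linked maternal share of in vitro males at 100%, against 97.5% for pooled bases. Apart from those 2 settings that ask for more reads or larger changes, the cause was not tested.

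Leaving out 1 library gave parental counts of 79 to 199 in ESCs, 112 to 160 at day 12, 113 to 119 at day 21, 48 to 57 at E13.5 and 47 to 59 at P0. The counts beyond 1.5 times were 79 without ESC_BJ1 replicate 2, 199 without ESC_JB6 replicate 1 and 112 without d12_JB6 replicate 2. Strain counts ran from 2946 to 3782, 2622 to 3001, 2774 to 2931, 4051 to 4271 and 4454 to 4781, and listed imprinted genes from 21 to 24, 33 to 37, 33 to 35, 35 to 37 and 34 to 37. Differences ran from 22 to 40 between day 12 and ESCs, 2 to 5 between day 21 and day 12, 8 to 16 between P0 and E13.5, 71 to 89 between day 12 and E13.5 and 73 to 94 between day 21 and P0. Between day 21 and day 12 the count was 2 without d12_JB6 replicate 2, and 3 without d12_BJ1 replicate 2, d21_BJ1 replicate 2, d21_JB6 replicate 1 or d21_JB6 replicate 2. Between P0 and E13.5 it was 8 without E13.5_BJ1 replicate 1 or P0_JB6 replicate 3, and 9 without E13.5_JB6 replicate 2 or P0_JB6 replicate 2. Expression counts ran from 7825 to 8337, 5230 to 5450, 7996 to 8138, 8357 to 8674 and 8878 to 9215. Where a cross was left with 1 library, that library is assumed to vary like the others. Replicate numbers gave no clear sign of pairing, as correlations of expression or allele ratio between libraries with the same number ran from −0.40 to 0.17. Between groups of 2 libraries both replicate numbers gave the same value, so each such pair of groups holds 1 contrast. Pairing by culture is therefore not excluded. DESeq2 size factors moved the median log2 fold of all genes by at most 0.097.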

Other observations

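The following values were chosen after the results were seen, and no explanation is offered for them. Transcription factor genes of other regions also moved in culture. From ESCs to day 12 Lmx1a, a factor of the caudal and midline neural tube, rose (log2 6.08 ± 0.742) and Gbx2, a factor of the hindbrain and of ESCs, fell (log2 −4.60 ± 0.39), with n = 4 each. Igfbp5, which binds insulin-like growth factors, rose from 1.82 ± 1.06 to 1650 ± 249 CPM, and Tdh, an enzyme of threonine breakdown in ESCs, fell (log2 −9.08 ± 0.444). From day 12 to day 21 Ptgds, a prostaglandin synthase of meninges and choroid plexus, rose to 251 ± 79.1 CPM, and Wnt1 fell (log2 −3.55 ± 0.351).

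From E13.5 to P0 the chromatin gene Hmga2 fell (log2 −6.39 ± 0.229) and the extracellular matrix gene Tnc rose (log2 4.78 ± 0.297), with n = 7 and 6. In day 21 cultures the keratin gene Krt15 reached 2720 ± 976 CPM (n = 4), and Epcam, an epithelial adhesion gene, was higher than at P0 (log2 9.41 ± 0.221). At day 12 the tight junction gene Cldn6 was higher than at E13.5 (log2 9.35 ± 0.357).

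The labelled replicates of ESC_JB6 were the least alike of all groups, with a chi-square per degree of freedom of 55.1, against 27.7 for d12_JB6 and 2.19 for the closest pair of libraries, within P0_BJ1. Paternal-labelled mitochondrial bases in JB6 were concentrated in some genes, with 21% for Cox2, 9.16% for Atpase6 and 1.86% for AK163440.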
